A study of Mus musculus with 12 samples.

How the data were processed

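RNA of whole duodenum from 12 male mice was measured on 12 one-colour (Cy3) Agilent mouse arrays, 3 for each of 4 groups: wild type given vehicle, wild type given the pentapeptide IIAEK, Akp3 knockout given vehicle and Akp3 knockout given IIAEK. Per the labels, the mice were 7 weeks old at the start, and vehicle was sodium carboxymethylcellulose at 5 g/L. The labels also say that IIAEK was given by mouth at 600 mg per kg body weight each day. Per the labels, the duodenum was taken after a fast of 8 h into RNAlater. The titles and the series design give 14 days of dosing for all groups, whereas the source labels of some samples give longer times; 14 days is used here. Per the labels' protocols, total RNA was labelled with a linear amplification kit from Agilent. How the knockout was made, and on which strain background, is not given in the sources used here.

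Per the file headers, the deposited scanner files were made with Feature Extraction 10.7.3.1 under a one-colour gene expression protocol. They hold for each spot a processed intensity, which is background-subtracted and spatially detrended but not scaled between arrays, next to the median raw and local background intensity. The authors' deposited value table gives log2 values whose making is not stated. Set against the scanner files, it matched log2 processed intensity shifted by each array's 75th percentile and centred on each probe's median over the 12 arrays. The correlation with values recomputed that way was at least 0.999996 on every array. Its direction is therefore that of the intensities, its scale is log2, and the level of a probe cannot be read from it after centring. Its column medians were -0.07, -0.08 and 0.13 for the wild-type vehicle arrays, -0.06, 0.04 and 0.07 for wild type under IIAEK, -0.05, -0.09 and 0.09 for knockout vehicle, and 0.12, -0.04 and 0.08 for knockout under IIAEK.

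Each array held 62976 spots, of which 3671 were controls and were left out. Spots that Feature Extraction had marked as non-uniform or as population outliers were also left out, which removed 22 of 56605 probes. Spots of the same probe were averaged on the log2 scale, and each array's 75th percentile was subtracted. Probe accessions were matched without versions to a RefSeq gene table of assembly GRCm38.p6. This named 32978 of the 56583 probes kept, for 22905 genes, of which 7894 had several probes, and left 23605 probes under the file's own identifier. The headers give an older genome build, so no coordinates are printed, and the table served only for names and for which genes neighbour each other. Probes had to be well above background on all 3 arrays of at least 1 group (32925 probes), and the probe with the highest mean over the 12 arrays stood for a gene. This left 26107 features, 15583 of them named genes and 10524 unnamed, with 5517 having over 1 probe past the filter.

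Between 55.9% and 64.0% of probes were well above background on an array, the 75th percentile of processed intensity lay between 195 and 465, and no spot was saturated. The number of arrays per group, 3, limits the precision. The median standard error of a log2 fold change was 0.243 between 2 groups, 0.344 for the difference between genotypes and 0.172 for averaged contrasts. Correlations across probes between replicates of a group ran from 0.953 to 0.990. Where a probe was not well above background on any array of the dimmer group, the fold is given as a lower bound, set by the lowest signal among probes well above background on each of its arrays.

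A linear model with 1 mean per group was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), so that all groups share an estimate of the spread. The 7 contrasts were IIAEK against vehicle in each genotype, the difference between these effects, knockout against wild type under each treatment, and the average effects of IIAEK and of the knockout. All tests are two-sided unless stated otherwise. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all 26107 features are called. For 46 gene lists written from textbook knowledge of the duodenum, of lipid absorption and of other cell types a sample could hold, limma's camera with a preset correlation of 0.01 was used, adjusted over the 46 lists. Next to it stand camera with an estimated correlation, fry, and the members called when adjusted over the list alone. The contrasts, lists, named genes and most alternatives were fixed before the data were examined.

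The rule for named genes was as follows. The alkaline phosphatase genes are named in every comparison, and Npc1l1, Abcg5, Abcg8, Abca1 and Slc15a1 under IIAEK; some other genes that the rule takes are not reported here. Up to 12 called genes with the highest and up to 12 with the lowest fold change are named, with groups not overlapping where 2 groups are compared. Where fewer than 10 were called, the 10 with the smallest p are named, or 8 for averaged contrasts and the difference. Of each list described, the called members or the 2 to 4 with the smallest p are named, and called genes within 10 Mb of Akp3 in the knockout comparisons. Unnamed and clone-named features are counted, not named.

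The procedure was tested on simulated data of the comparison of IIAEK with vehicle in wild type, over 26107 features and 5 simulations. Changes of 2-fold were recovered in 39.1%, 4-fold in 87.2% and 16-fold in 98.5% of genes, with 7.8 unchanged genes called per simulation. A list shifted by 0.5 log2 units was called in 5 of 5 simulations, with 1 call of another list in all. The simulated genes and arrays were independent, without slide effects or genes that vary together. These counts therefore do not give the rate of false list calls in the real arrays. The shares recovered also depend on how many genes were changed in each simulation.

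The arrays came from 2 slides, each scanned on its own day, so slide and scan cannot be told apart. Slide 1 held 7 arrays: wild-type vehicle 1 and 2, wild-type IIAEK 1 and 2, knockout vehicle 1 and knockout IIAEK 1 and 2. Slide 2 held the other 5. With slide in the model, 6871 features differed between slides. Values with slide as a block or within each slide are therefore given with the counts, the lists and some of the named genes. Within slide 2 alone, 5 arrays leave 1 residual degree of freedom. Knockout vehicle has 1 array on slide 1, and each group but knockout vehicle has 1 on slide 2, so values within a slide rest on single arrays there. Replicate numbers recur across groups, and no label says what they share. Correlations of same-numbered arrays' deviations from their group means were 0.361, 0.165 and 0.43 for wild type under IIAEK against vehicle and 0.539, 0.121 and 0.178 for knockout against wild type under vehicle, so the numbers count as pairs there. Slide was not removed from these correlations, and number 3 of both wild-type groups lay on slide 2, so slide may enter them. The correlations were 0.0462, -0.252 and -0.216 for IIAEK in knockout, and 0.0366, 0.47 and 0.699 for knockout under IIAEK.

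Alternatives were normexp background correction with an offset of 50, quantile normalization, the deposited value table, no filter on dim probes, only probes well above background on all arrays, the mean of a gene's probes, no intensity trend, a robust trend, only the groups compared, slide or replicate number as a block, each slide alone, array weights, a 1.5-fold minimum and each array left out. The scanner files hold no mean raw intensity, so normexp was run on the median raw intensity with the median local background. Gene-by-gene array weights, and the mean of the stomach-type list alone or with that of the pancreatic list as covariates, were chosen after seeing the data. Under each scaling the median of all genes moved by under 0.1 log2 units in every contrast. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.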

Results

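Duodenal RNA was measured in 12 male mice on 1 array per mouse. The 4 groups of 3 mice crossed genotype (wild type or Akp3 knockout) with 14 days of oral vehicle or IIAEK, a pentapeptide that the labels call cholesterol-lowering. Akp3 encodes a duodenal form of intestinal alkaline phosphatase, a brush border enzyme that removes phosphate groups from lipids, nucleotides and bacterial endotoxin. The design asks whether the peptide changes duodenal expression and whether any such change needs Akp3. Between 55.9% and 64.0% of probes were well above background on an array, and the analysis covered 26107 features, 15583 of them named genes. All levels are log2 intensities relative to the array's 75th percentile, so a level of 0 is that percentile. Fold changes are log2, treated minus vehicle or knockout minus wild type, with adjusted p from limma.

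Akp3 separated the genotypes on every array. Its level was 2.27, 2.04 and 1.70 in wild type under vehicle and 1.29, 1.05 and 2.72 in wild type under IIAEK, against -4.01, -3.80 and -4.23 in knockout under vehicle and -4.64, -4.42 and -4.90 in knockout under IIAEK. The probe was well above background on all 6 wild-type arrays and on 2 and 1 of the 3 knockout arrays under vehicle and IIAEK. Where the probe lies relative to the deleted part of the gene is not given in the sources used here. A second Akp3 probe, not well above background on any knockout array, was at least 93.8-fold lower in the knockout under vehicle and 78.8-fold under IIAEK. Alppl2, the gene for an embryonic-type alkaline phosphatase that is a close neighbour of Akp3, had levels of 0.78, 0.56, 0.72, -0.08, -0.47 and 1.56 in wild type and of -1.76, -1.25, -1.47, -2.13, -2.04 and -1.06 in knockout. Alpi, which encodes the other intestinal alkaline phosphatase, stayed between 6.12 and 7.49 on all arrays. Alpl, the tissue-nonspecific form, lay between -3.48 and -2.48.

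**Figure D1:**
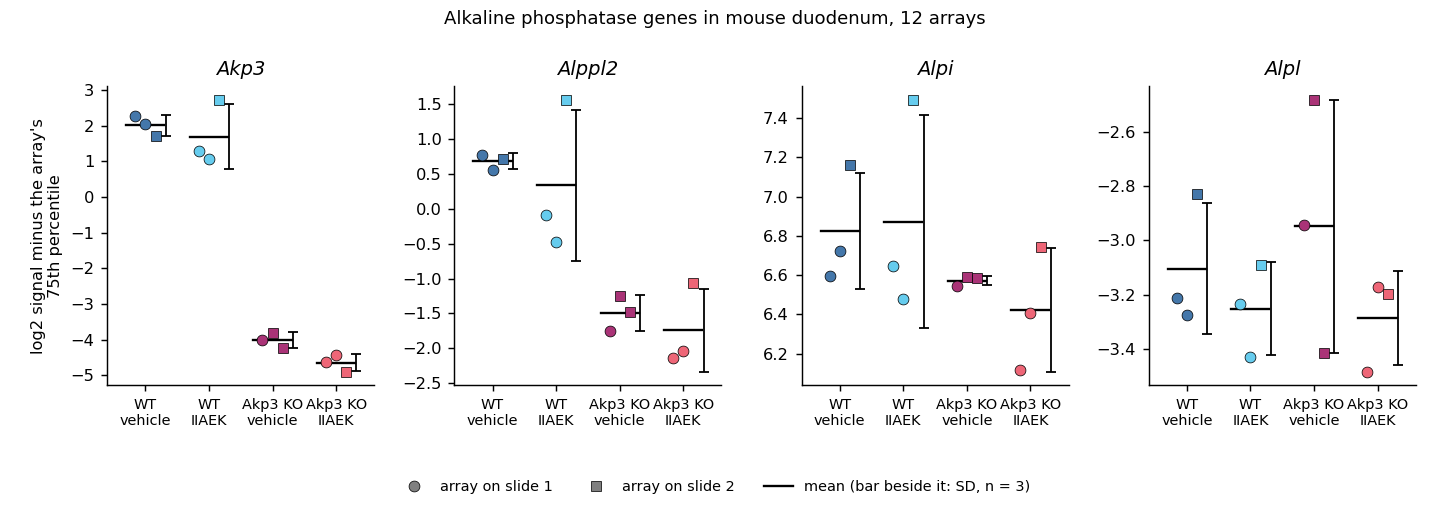
Levels of Akp3, Alppl2, Alpi and Alpl on each of the 12 arrays (vertical axis, log2 intensity relative to the array's 75th percentile), by group; circles are arrays of slide 1, squares arrays of slide 2, and bars the group mean and SD of 3 arrays. Akp3 lies between 1.05 and 2.72 in wild type and between -4.90 and -3.80 in knockout.

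The samples also differed in genes of neighbouring organs. Mucous and surface genes of stomach and Brunner's glands (10 genes such as Gkn1, Gkn2, Muc5ac and Tff1) averaged between 2.96 and 4.39 on 6 arrays and between -3.24 and -1.32 on the other 6. The high arrays were all 3 of wild type under vehicle, 1 of wild type under IIAEK (replicate 3), 1 of knockout under vehicle (replicate 1) and 1 of knockout under IIAEK (replicate 3). Genes of the exocrine and endocrine pancreas (32 genes, such as the trypsinogens Prss1 and Prss2) averaged 2.17 on the array of wild-type vehicle 1 and between 6.76 and 8.84 on the others. Where another list described below loses its call once both averages enter the model as covariates, this is given with the list or in the closing part. The covariates also add calls of lists that are otherwise not called: 10 for IIAEK in wild type, 8 for IIAEK in knockout, 4 for the difference between genotypes, 5 for knockout under vehicle, 1 for knockout under IIAEK, 9 for averaged IIAEK and 4 for averaged knockout.

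**Figure D2:**
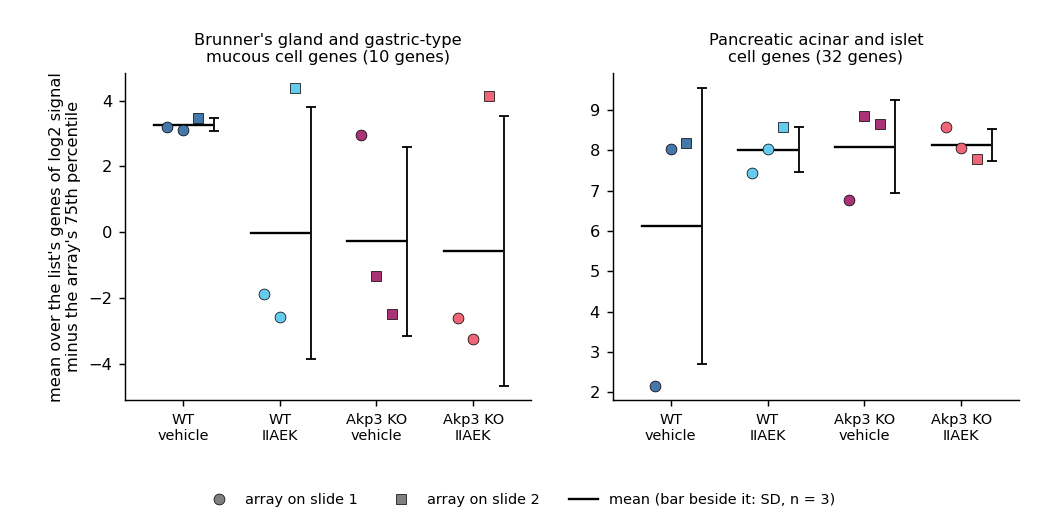
Mean log2 level of 10 stomach-type genes and of 32 pancreatic genes on each array (vertical axis, relative to the array's 75th percentile), by group; circles are arrays of slide 1 and squares arrays of slide 2. Stomach-type genes lie between 2.96 and 4.39 on 6 arrays and between -3.24 and -1.32 on the other 6.

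Comparing knockout with wild type under vehicle asks what the loss of Akp3 does in untreated mice. Akp3 fell by 6.01 (SE 0.37, adjusted p = 4.82e-05), and by camera with its preset correlation the interferon-induced, T-cell and macrophage genes shifted upward as groups, while glucocorticoid targets, heat shock genes and B-cell genes shifted downward. With an estimated correlation 0 lists were called (smallest adjusted p = 0.572). The glucocorticoid-induced leucine zipper gene Tsc22d3 (-1.11), the stress-induced mTOR inhibitor Ddit4 (-1.44) and the kinase gene Sgk1 (-1.67) led the glucocorticoid and heat shock groups together with the chaperone genes Hspa1b (-2.27) and Hsph1 (-0.93). None of these single genes passed the adjustment over all genes.

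In the genome-wide test under vehicle, 2 features passed, both lower: Akp3 and an unnamed expressed sequence tag (-7.35, at least 47.2-fold lower). At an unadjusted p under 0.05 there were 560 higher and 446 lower features. Akp3 was -6.07 with slide as a block (adjusted p = 1.52e-04), -6.16 within slide 1 and -5.71 within slide 2. The count of features was 2 with slide as a block, 4 within slide 1 and 80 within slide 2, and it rose to 18 without wild-type vehicle 3. Next came Rgp1, a membrane traffic gene (-2.19, SE 0.36), the chromatin gene Banp (-1.55, SE 0.26) and the transcriptional repressor gene Bcl6 (-1.10, SE 0.20), with adjusted p from 0.382 to 0.408. Glrp1 (-2.00, at least 1.11-fold lower), the nucleolar gene Utp14b (-1.07), the lipoxygenase gene Alox15 (1.60, at least 1.46-fold higher), the renin gene Ren2 (2.65), Tsc22d3 (-1.11) and the lymphocyte egress receptor gene S1pr1 (-1.04) had adjusted p from 0.408 to 0.466. A second Rgp1 probe differed by 0.10. Alppl2 was -2.18 (adjusted p = 0.665; with slide as a block -2.45, adjusted p = 0.0748), Alpi -0.26 and Alpl 0.16.

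Camera called 19 of 46 lists under vehicle, 9 higher and 10 lower, 18 with slide as a block, and 0 with an estimated correlation. The alkaline phosphatase list had a median of -1.22 (adjusted p = 4.34e-06, or 0.572 with an estimated correlation), with 2 of 4 members lower when adjusted over the list alone. It was the 1 list that fry called. The list holds Akp3, the deleted gene, so its call follows from the genotype and does not show a decrease of the whole family. Its members Alpi and Alpl were at -0.255 and 0.156. Interferon-response genes had a median of 0.27, with 34 of 36 above 0 (adjusted p = 3.52e-07, or 0.657 with an estimated correlation). Their median was 0.31 with slide as a block (adjusted p = 3.96e-06), 0.28 within slide 1 and 0.17 within slide 2. The T-cell chemokine gene Cxcl9 (0.80), the translation inhibitor gene Ifit2 (0.51) and the GTPase gene Gbp6 (0.64) had the smallest p. Macrophage, dendritic cell and granulocyte genes had a median of 0.25 with 17 of 18 above 0 (adjusted p = 4.30e-04, or 0.657 with an estimated correlation; -0.01 within slide 1 and 0.51 within slide 2), and the eosinophil granule gene Prg2 (0.87) passed when adjusted over the list alone. Without knockout vehicle 2 that call ended (adjusted p = 0.0748). Interferon and macrophage genes were at adjusted p = 0.0878 for both lists with the tissue scores as covariates.

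Glucocorticoid and fasting-response genes had a median of -0.33 with 13 of 19 below 0 (adjusted p = 9.86e-05, or 0.657 with an estimated correlation; -0.36 with slide as a block, -0.27 within slide 1 and -0.33 within slide 2). Tsc22d3 and Ddit4 passed when adjusted over the list alone, and the list stayed called without any 1 array and with both tissue scores (adjusted p = 4.85e-04). Immediate early and heat shock genes had a median of -0.27 with 15 of 20 below 0 (adjusted p = 7.04e-04, or 0.657 with an estimated correlation; -0.29 with slide as a block, -0.26 within slide 1 and -0.09 within slide 2), a call that ended without knockout vehicle 1 (adjusted p = 0.0665). Hspa1b passed when adjusted over the list alone. T-cell and intraepithelial lymphocyte genes were higher (median 0.34, adjusted p = 0.00199, or 0.692 with an estimated correlation; 0.33 with slide as a block, 0.51 within slide 1 and -0.03 within slide 2), with the epithelial retention integrin gene Itgae (0.52) and the killer-cell coreceptor gene Cd8b1 (0.55) leading. That call ended without wild-type vehicle 1 (adjusted p = 0.116), knockout vehicle 1 (0.0516) or knockout vehicle 2 (0.0695), and with the tissue scores as covariates (0.272).

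Drug-metabolizing and NRF2-target genes were higher under vehicle (median 0.25, adjusted p = 4.30e-04, or 0.708 with an estimated correlation; 0.35 with slide as a block, 0.28 within slide 1 and 0.17 within slide 2), as were nuclear genes of oxidative phosphorylation (median 0.17, 40 of 41 above 0, adjusted p = 7.04e-04, or 0.783 with an estimated correlation; 0.27 with slide as a block, 0.18 and 0.21 within the slides). With both tissue scores as covariates these medians were -0.01 and -0.01, with adjusted p = 0.914 and 0.862. With quantile normalization the oxidative phosphorylation median was 0.06 (adjusted p = 0.217). Genes of the pancreas (median 1.94, adjusted p = 1.44e-09) were higher and stomach-type genes (median -3.29, adjusted p = 3.34e-05) lower, both at adjusted p = 0.657 with an estimated correlation, following the arrays named above. The pancreatic median was 1.48 with slide as a block, 1.93 within slide 1 and 0.49 within slide 2, and its call ended without wild-type vehicle 1 (adjusted p = 0.353). The stomach-type median was -4.21 with slide as a block, -0.09 within slide 1, -4.94 within slide 2 and -2.02 with normexp. B-cell genes were lower (median -0.70, adjusted p = 0.00724, or 0.657 with an estimated correlation and 0.0875 with slide as a block; -0.63 within slide 1, 0.46 within slide 2 and -0.28 with normexp), and the call ended without wild-type vehicle 1 (adjusted p = 0.155), wild-type vehicle 2 (0.142) or knockout vehicle 1 (0.0665) and with the tissue scores (0.118).

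Under IIAEK, the knockout arrays again had low Akp3 (-6.34, SE 0.37, adjusted p = 2.72e-05), and genes of T cells and of the cell cycle shifted upward as groups while drug-metabolizing and brush border enzyme genes shifted downward, by camera with its preset correlation. With an estimated correlation these 4 groups were at adjusted p = 0.564, 0.564, 0.832 and 0.832. The same 2 features as under vehicle passed, with the unnamed tag at -6.69 (at least 34.6-fold lower), beside 108 higher and 235 lower features at an unadjusted p under 0.05. Akp3 was -6.34 with slide as a block (adjusted p = 7.27e-05), which could not move it because each slide held as many arrays of both groups. Akp3 was -5.70 within slide 1 and -7.62 within slide 2. The count was 2 with slide as a block, 8 within slide 1, 14 within slide 2 and 4 without knockout IIAEK 3. Rgp1 (-2.28, with the second probe at -0.15), the cilia gene Cfap100 (-2.28, at least 2.11-fold lower), Utp14b (-1.13), the kinase gene Stk25 (-1.48), the guanine exchange factor gene Ngef (-0.62), Glrp1 (well above background on 1 of the 6 arrays), Alppl2 (-2.08), the AP-1 gene Fosl2 (-0.48) and the peptide-amidating enzyme gene Pam (2.39) had the next smallest p, with adjusted p from 0.435 to 1. Alpi was -0.45 and Alpl -0.03, a sign that changed between scalings.

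Camera called 14 lists here, 7 in each direction, 12 with slide as a block and 0 with an estimated correlation. The alkaline phosphatase list had a median of -1.27 with all 4 members below 0 (adjusted p = 1.32e-11, or 0.0845 with an estimated correlation). It was again the only list called by fry, and it holds the deleted gene Akp3, so this call too follows from the genotype. Its members Alpi and Alpl were at -0.45 and -0.03. T-cell genes had a median of 0.27 with 17 of 21 above 0 (adjusted p = 2.46e-06, or 0.564 with an estimated correlation; 0.53 within slide 1 and -0.14 within slide 2), led by the T-cell receptor modulator gene Cd5 (0.72) and Cd8b1 (0.69). Their call ended without knockout IIAEK 1 (adjusted p = 0.267). Cell cycle genes had a median of 0.16 with 30 of 35 above 0 (adjusted p = 7.02e-06, or 0.564 with an estimated correlation; 0.07 and 0.42 within the slides), and without knockout IIAEK 3 the adjusted p was 0.759. Drug-metabolizing genes (median -0.24, 32 of 37 below 0, adjusted p = 2.03e-04; -0.09 and -0.39 within the slides) and brush border digestive enzymes such as trehalase (Treh, -0.36) and lactase (Lct, -0.45) (median -0.17, 17 of 18 below 0, adjusted p = 0.00293; -0.14 and -0.50 within the slides) were both at adjusted p = 0.832 with an estimated correlation. These calls ended without wild-type IIAEK 2 (adjusted p = 0.592 and 0.145) or knockout IIAEK 3 (0.773 and 0.891). The array of knockout IIAEK 3 stood apart in tissue markers. It had the lowest mean of brush border enzymes (3.00, others from 3.45) and of enterocyte villus genes (5.92, others from 6.11), and the highest of smooth muscle (3.03, others up to 2.49), matrix (2.40, others up to 1.94), endothelial (0.46, others up to 0.17) and enteric neuron genes (0.27, others up to 0.07). Macrophage genes (median 0.17, adjusted p = 0.00175, or 0.564 with an estimated correlation; 0.13 and 0.21 within the slides) lost the call without wild-type IIAEK 3 (0.174) or knockout IIAEK 2 (0.0651). Slide as a block left each of these medians as it was, because each slide held as many wild-type as knockout arrays under IIAEK.

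Averaged over both treatments, 5 features were lower in the knockout and 0 higher by limma, beside 357 higher and 435 lower features at an unadjusted p under 0.05. Besides Akp3 (-6.18, SE 0.26, adjusted p = 8.39e-07) and the unnamed tag, which was not well above background on any knockout array, these were Rgp1, which serves retrograde traffic to the Golgi (-2.23, SE 0.25, adjusted p = 0.0204), Utp14b (-1.10, SE 0.14, adjusted p = 0.0414) and a cDNA clone without a gene name (-2.30, adjusted p = 0.0414). The knockout arrays were lower for Rgp1 in both treatments, but its second probe differed by -0.03, and the mean of its probes gave -1.13 (adjusted p = 0.615). Within the slides, Rgp1 was -2.16 and -2.39, and with slide as a block -2.32 (adjusted p = 0.00319). Utp14b, a gene of ribosomal RNA processing within 10 Mb of Akp3, was -1.06 with slide as a block (adjusted p = 0.0121), -1.06 within slide 1 and -1.03 within slide 2, the last 2 without passing. It was -0.34 with normexp (adjusted p = 1), and its call also ended without the filter on dim probes (0.0982), with replicate number as a block (0.0691) and with both tissue scores (0.0967). Leaving out 1 array gave Rgp1 adjusted p from 0.0522 to 0.112 without wild-type vehicle 1 or 2, any knockout vehicle array or knockout IIAEK 1 or 2, and Utp14b from 0.0522 to 0.198 without any array but wild-type IIAEK 3. The count was 8 with slide as a block and 8 without the intensity trend. It was 12 within slide 1 and 49 within slide 2, and it was 2 without wild-type vehicle 1 or 2, knockout vehicle 1 or 2 or knockout IIAEK 2, 3 without knockout vehicle 3, and 10 without wild-type IIAEK 3.

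Several of the genes just short of the threshold lay on chromosome 1 close to Akp3. Glrp1 (adjusted p = 0.0604), Ngef (-0.61, adjusted p = 0.0668) and Alppl2 (-2.13, SE 0.32, adjusted p = 0.0714) did not pass. Glrp1 was not well above background on any knockout array, so its fold is not given here. Alppl2 passed with slide as a block (-2.27, adjusted p = 0.00555). Ren2 (2.19) and Bcl6 (-0.86) followed at adjusted p = 0.114. Alpi (-0.35) and Alpl (0.06) did not change detectably.

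**Figure D3:**
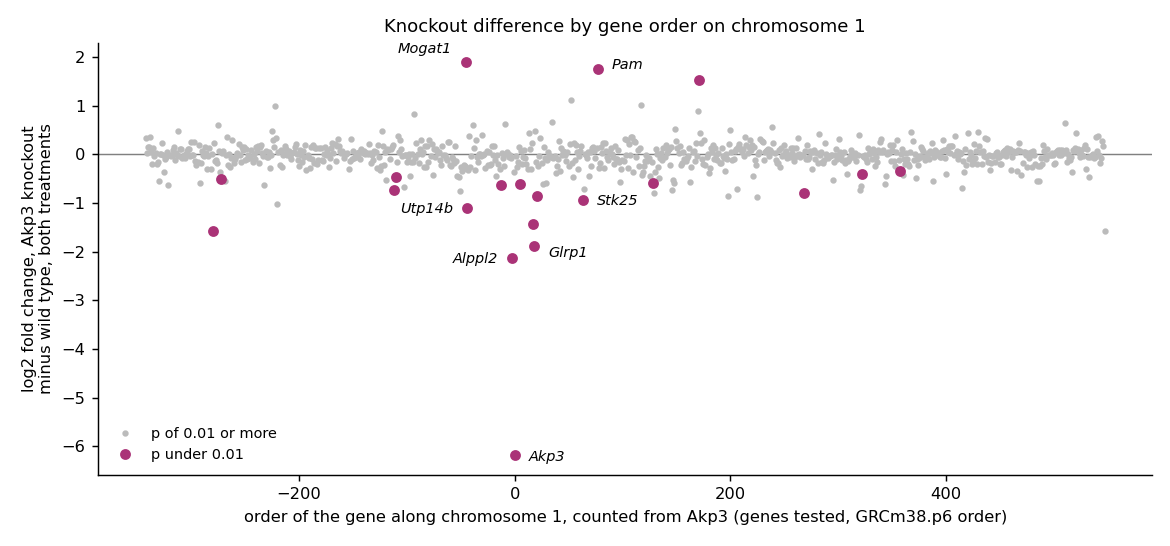
Knockout minus wild type log2 fold change, averaged over treatments, of each named gene on chromosome 1 (vertical axis) against its position in gene order counted from Akp3 (horizontal axis); coloured points have a limma p under 0.01. Akp3 (-6.18), Alppl2 (-2.13) and Utp14b (-1.10) lie lower in the knockout, and Mogat1 (1.89) and Pam (1.76) higher.

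Of the 13 lists that camera called in the averaged contrast (7 higher and 6 lower; 18 with slide as a block, 0 with an estimated correlation), those of interferon, T-cell, macrophage and mucosal defence genes were higher in the knockout. Alkaline phosphatases, a list that holds the deleted gene Akp3, had a median of -1.24 (adjusted p = 1.58e-09, or 0.149 with an estimated correlation). With slide as a block their median was -1.35. Interferon-response genes had a median of 0.23 with 33 of 36 above 0 (adjusted p = 6.56e-09, or 0.729 with an estimated correlation; 0.26 with slide as a block, 0.31 within slide 1 and -0.06 within slide 2), led by the antiviral genes Oas1a (0.27), Isg15 (0.51) and Ifit2 (0.31). T-cell genes had a median of 0.24 (adjusted p = 4.14e-07, or 0.729 with an estimated correlation; 0.30 with slide as a block, 0.47 and -0.14 within the slides), led by Cd5 (0.53) and Cd8b1 (0.62). Macrophage genes had a median of 0.18 with 18 of 18 above 0 (adjusted p = 4.42e-06, or 0.56 with an estimated correlation; 0.20 with slide as a block, 0.07 and 0.38 within the slides), with Prg2 (0.62) passing when adjusted over the list alone. These 4 lists stayed called without any 1 array and with both tissue scores as covariates. Genes of mucosal defence (median 0.25, adjusted p = 0.00249, or 0.729 with an estimated correlation; 0.20 with slide as a block, 0.21 and 0.11 within the slides), led by the acute-phase gene Saa3 (0.84) and the oxidase maturation gene Duoxa2 (0.92), did not stay called without knockout IIAEK 1 (adjusted p = 0.145) or with both tissue scores (0.427).

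IIAEK against vehicle in wild type asks what the peptide does when Akp3 is present. The sterol exporter genes Abcg5 and Abcg8, whose products pump absorbed cholesterol back into the gut lumen, were 0.44 (SE 0.21) and 0.62 (SE 0.23) above vehicle. The Abcg8 level was 4.42, 4.33 and 3.68 under vehicle and 5.17, 4.53 and 4.58 under IIAEK, without overlap, an outcome that chance gives for 10% of genes with 3 arrays against 3. Neither passed adjustment over all genes (adjusted p = 0.999), nor with slide as a block (adjusted p = 0.787 for both). The cholesterol uptake channel gene Npc1l1 (0.15, SE 0.15), the basolateral cholesterol exporter gene Abca1 (0.31, SE 0.24) and the oligopeptide transporter gene Slc15a1 (0.13, SE 0.59) did not pass either (adjusted p = 0.999). Slc15a1 was 1 of the genes that differed between slides (-1.31, adjusted p = 0.00341). Within slides 1 and 2, Abcg5 was 0.46 and 0.40, Abcg8 0.471 and 0.905, and Npc1l1 0.226 and 0.00158. Abca1 (0.55 and -0.19) and Slc15a1 (0.28 and -0.18) turned between the slides.

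**Figure D4:**
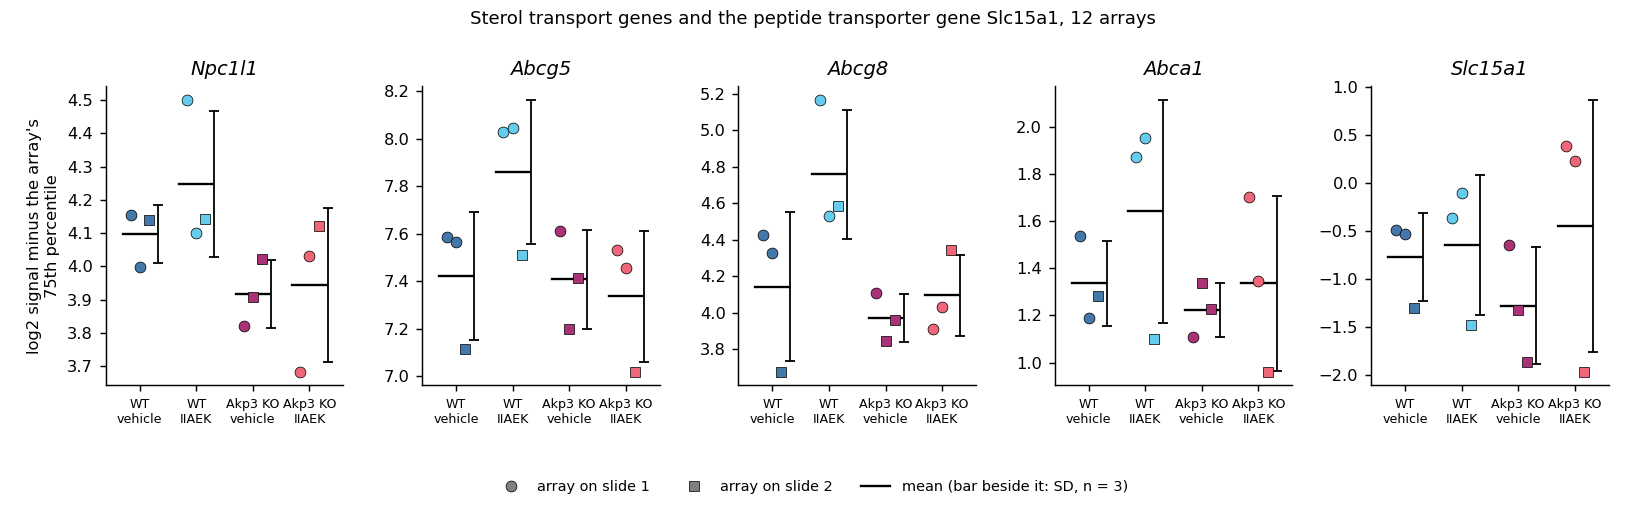
Levels of Npc1l1, Abcg5, Abcg8, Abca1 and Slc15a1 on each array (vertical axis, log2 intensity relative to the array's 75th percentile), by group; circles are arrays of slide 1, squares arrays of slide 2, and bars the group mean and SD of 3 arrays. Abcg8 in wild type lies between 3.68 and 4.42 under vehicle and between 4.53 and 5.17 under IIAEK.

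By limma, 0 genes passed for IIAEK in wild type (0 without the intensity trend), with 444 higher and 375 lower at an unadjusted p under 0.05. Within slide 1 the count was 257, within slide 2 and with slide as a block 0, and without wild-type vehicle 3 it was 17. The smallest p belonged to the osmolyte transporter gene Slc5a3 (-0.87, SE 0.18), the apoptosis gene Bbc3 (0.75, SE 0.15) and S1pr1 (-0.98, SE 0.20). Bnip5 (1.38), the B-cell chemokine gene Cxcl13 (-2.07, SE 0.45), the signalling adaptor gene Grb7 (0.60), Uspl1 (-0.45) and Alox15 (1.25, at least 1.14-fold higher) followed. So did the mucin gene Glycam1 (-1.78, SE 0.44) and the mitochondrial carrier gene Slc25a48 (-1.37, at least 1.43-fold lower). All of these genes were at adjusted p = 0.999. Of the alkaline phosphatases, Akp3 was -0.31, Alppl2 -0.35, Alpi 0.05 (a sign that changed between scalings) and Alpl -0.15. Akp3, Alppl2 and Alpi turned between the slides, with -0.98, -0.94 and -0.10 within slide 1 and 1.02, 0.85 and 0.33 within slide 2. Their list was not called (median -0.23, adjusted p = 0.301). It was lower within slide 1 (-0.52, adjusted p = 0.00621) and without wild-type IIAEK 3 (-0.55, adjusted p = 0.00232), and higher within slide 2 (0.59, adjusted p = 0.0265).

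As groups, drug-metabolizing and oxidative phosphorylation genes were higher and cell cycle, glucocorticoid-response and heat shock genes lower under IIAEK in wild type, by camera with its preset correlation and not with an estimated one. Camera called 14 lists, 6 higher and 8 lower, of which 11 stayed called with slide as a block. Each of the 14 had adjusted p = 0.734 with an estimated correlation, and fry called 0. Slide as a block left their medians unchanged, because each slide held as many vehicle as IIAEK arrays of wild type. Drug-metabolizing and NRF2-target genes had a median of 0.45 with 34 of 37 above 0 (adjusted p = 1.37e-07; 0.66 within slide 1 and -0.07 within slide 2), led by the carboxylesterase gene Ces1d (0.69) and the cytochrome P450 gene Cyp2c55 (1.43). Oxidative phosphorylation genes had a median of 0.25 with 41 of 41 above 0 (adjusted p = 1.46e-06; 0.32 and 0.11 within the slides). With quantile normalization it was 0.09 (adjusted p = 0.0169). Cell cycle genes had a median of -0.21 with 31 of 35 below 0 (adjusted p = 3.03e-06; -0.26 and -0.18 within the slides), led by the ribonucleotide reductase gene Rrm1 (-0.46) and the spindle gene Tpx2 (-0.67). These 3 lists stayed called without any 1 array, but their calls ended with both tissue scores as covariates (adjusted p = 0.0647, 0.0776 and 0.255).

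**Figure D5:**
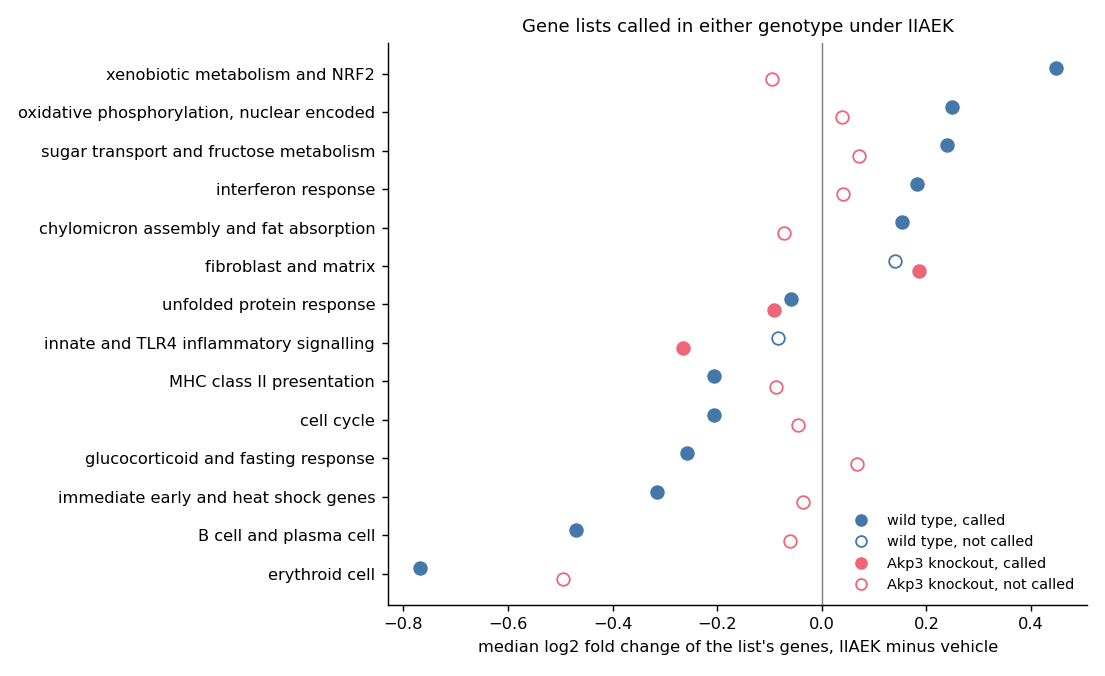
Median log2 fold change of IIAEK against vehicle (horizontal axis) in wild type and in knockout for the 14 gene lists called in either genotype other than the stomach-type and pancreatic lists; filled symbols are lists that camera called with the preset correlation. Drug-metabolizing genes have a median of 0.45 in wild type, and the list of innate inflammatory genes -0.27 in knockout.

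Glucocorticoid and fasting-response genes had a median of -0.26 with 14 of 19 below 0 (adjusted p = 1.24e-04, or 0.734 with an estimated correlation; -0.35 and -0.19 within the slides), led by Tsc22d3 (-0.65), Ddit4 (-0.98) and Fkbp5 (-0.63). The list stayed called without any 1 array and with both tissue scores (adjusted p = 1.58e-04). Immediate early and heat shock genes had a median of -0.32 (adjusted p = 2.45e-04; -0.36 within slide 1 and 0.42 within slide 2), with Hsph1 (-1.11) passing when adjusted over the list alone, and the call ended without wild-type IIAEK 1 (adjusted p = 0.0656). Unfolded protein response genes such as the chaperone gene Hspa5 (-0.26) had a median of -0.06 (adjusted p = 0.0498; -0.17 and -0.02 within the slides, and -0.12 with quantile normalization). The call ended without wild-type vehicle 2 (0.211), wild-type vehicle 3 (0.278), wild-type IIAEK 1 (0.787) or wild-type IIAEK 2 (0.0733) and with replicate number as a block (0.0517). B-cell genes such as Cd79b (-1.54) had a median of -0.47 (adjusted p = 2.14e-04; -0.67 and 0.01 within the slides, and -0.29 with normexp), not called without wild-type IIAEK 3 (0.0564). Their mean was 1.498 and 1.242 on wild-type vehicle 1 and 2, but -0.534 on wild-type vehicle 3. Under IIAEK it was 0.199, -0.293 and -0.513, so the shift rests on 2 vehicle arrays. MHC class II genes had a median of -0.21 (adjusted p = 0.0498, or 0.0768 with slide as a block, 0.0806 with replicate number as a block and 0.197 with the tissue scores; -0.31 and 0.03 within the slides). That call ended without wild-type vehicle 1 (0.214), wild-type vehicle 2 (0.122), wild-type IIAEK 2 (0.37) or wild-type IIAEK 3 (0.0548). Haemoglobin and other erythroid genes had a median of -0.77 with 6 of 6 below 0 (adjusted p = 0.00177; -0.26 and -1.89 within the slides), not called without wild-type vehicle 3 (0.45) or wild-type IIAEK 1 (0.148).

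Interferon-response genes were higher under IIAEK in wild type too (median 0.18, 31 of 36 above 0, adjusted p = 8.86e-04, or 0.734 with an estimated correlation; 0.22 and 0.18 within the slides), led by Cxcl9 (0.83) and the transcription factor gene Irf1 (0.48). Without wild-type vehicle 1 (adjusted p = 0.0538) or wild-type IIAEK 3 (0.0755), and with the tissue scores (0.649), the call ended. Genes of chylomicron assembly (median 0.15, 25 of 28 above 0, adjusted p = 0.0463; 0.35 and -0.12 within the slides) and of sugar transport (median 0.24, 12 of 13 above 0, adjusted p = 0.0498; 0.40 and -0.21 within the slides) lost their calls with slide as a block (adjusted p = 0.0681 and 0.0894), with replicate number as a block (0.0546 and 0.075), and with the tissue scores (0.467 and 0.854). With quantile normalization their medians were 0.01 and 0.07 (adjusted p = 0.558 and 0.282). Both calls also ended without wild-type vehicle 1 (0.523 and 0.579), wild-type vehicle 2 (0.427 and 0.148), wild-type IIAEK 1 (0.0849 and 0.0991), wild-type IIAEK 2 (0.126 and 0.0635) or wild-type IIAEK 3 (0.057 and 0.0755). Pancreatic genes had a median of 1.96 (adjusted p = 2.09e-09; 2.82 and 0.39 within the slides), not called without wild-type vehicle 1 (0.299). Stomach-type genes had one of -3.56 (adjusted p = 9.77e-06; -5.66 and 0.84 within the slides, and -2.05 with normexp). Cholesterol synthesis genes, which SREBP2 induces when cell cholesterol is low, had a median of -0.05 over 23 genes (adjusted p = 0.323). They were called lower within slide 1 (-0.10, adjusted p = 0.0142; 0.14 within slide 2) and without wild-type IIAEK 3 (-0.09, adjusted p = 0.0336). Sterol transport and LXR-target genes had a median of 0.09 over 21 (adjusted p = 0.290; 0.20 and 0.00 within the slides). They were called higher with the stomach-type score (0.16, adjusted p = 0.0467), with both tissue scores (0.17, adjusted p = 0.0312) and without wild-type IIAEK 2 (0.12, adjusted p = 0.0357), and were at adjusted p = 0.734 with an estimated correlation.

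In the knockout, IIAEK against vehicle asks what the peptide does without Akp3. Genes of innate inflammatory signalling were lower as a group, led by the alarmin gene Il33 (-1.09), the endotoxin coreceptor gene Cd14 (-0.75), the interleukin-1 antagonist gene Il1rn (-0.68) and the neutrophil chemokine gene Cxcl1 (-2.10, at least 2.95-fold lower). That call was by camera with its preset correlation, and it ended with an estimated one (adjusted p = 0.913) and without knockout vehicle 2 (0.145). The chitinase-like genes Chil3 (-4.97, SE 1.05) and Chil4 (-5.14, at least 11.4-fold lower) had some of the smallest p of single genes. Of the sterol transport genes, Npc1l1 was at 0.03, Abcg5 at -0.07, Abcg8 at 0.13 and Abca1 at 0.11, and Slc15a1 was at 0.83 (adjusted p = 1). Within slides 1 and 2, Abcg8 was -0.13 and 0.44, Abca1 0.41 and -0.32, and Slc15a1 0.96 and -0.38. Npc1l1 was 0.04 and 0.16 there, and Abcg5 -0.12 and -0.29. Slc15a1 differed between slides (-1.31), and slide 2 held more knockout vehicle than knockout IIAEK arrays, so slide may enter its 0.83.

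No single gene passed in the knockout. The limma count was 0 (0 without the intensity trend), with 213 higher and 286 lower at an unadjusted p under 0.05, and it was 58 within slide 1, 255 within slide 2 and 0 with slide as a block. The first 2 counts set 2 arrays against 1, with knockout vehicle 1 alone on slide 1 and knockout IIAEK 3 alone on slide 2. The testis protease gene Adam24 (-2.42, at least 1.91-fold lower), Veph1 (1.18), the inflammatory caspase gene Casp4 (-1.15), Unc80 (1.48, at least 1.43-fold higher), the ubiquitin ligase gene Rnf183 (-1.08), the pseudogene Gpx2-ps1 (-1.10), Stk25 (-0.98) and Lars (-0.52) were next after the chitinase-like genes, all at adjusted p = 1. Akp3, close to background here, was -0.64, Alppl2 -0.25, Alpi -0.15 and Alpl -0.34. Alppl2 and Alpi were -0.32 and -0.28 within slide 1 and 0.30 and 0.16 within slide 2. The alkaline phosphatase list, which includes the deleted gene, was not called by camera (median -0.293, adjusted p = 0.087). It was called lower with quantile normalization (-0.315, adjusted p = 0.0489) and without knockout vehicle 3 (-0.406, adjusted p = 0.024). Its median was -0.355 within slide 1 and -0.0452 within slide 2.

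Camera called 3 lists in the knockout, and 0 with an estimated correlation (adjusted p = 0.913 for each). Innate inflammatory genes had a median of -0.27 with 14 of 21 below 0 (adjusted p = 3.52e-04; -0.22 with slide as a block, where adjusted p was 0.00461, -0.11 within slide 1, -0.49 within slide 2 and -0.17 with normexp), not called without knockout vehicle 2 (adjusted p = 0.145). Unfolded protein response genes had a median of -0.09 (adjusted p = 0.0279, or 0.358 with slide as a block; 0.05 and -0.35 within the slides), led by the glutathione-cleaving enzyme gene Chac1 and the disulfide isomerase gene Pdia6 (-0.34). Fibroblast and matrix genes had a median of 0.19 with 19 of 23 above 0 (adjusted p = 0.0315; 0.22 with slide as a block, -0.10 and 0.65 within the slides), led by Fbln1 (0.31). The unfolded protein call ended without knockout vehicle 2 (adjusted p = 0.373), knockout IIAEK 2 (0.0622) or knockout IIAEK 3 (0.156), and the matrix call without knockout vehicle 1 (0.154), knockout vehicle 2 (0.0751) or knockout IIAEK 3 (0.154), the array on which muscle, endothelial and neuron genes were highest too. The number of called lists moved more than this. It was 14 with normexp, 11 with quantile normalization, 12 with the stomach-type score, 11 with both tissue scores and 5 with slide as a block. Chylomicron and enterocyte villus genes were called lower with normexp (adjusted p = 9.24e-04 and 0.00615), quantile normalization (0.0124 for both) and both tissue scores (0.03 and 0.0485), against 0.0639 and 0.129 here. The number was 15 without knockout IIAEK 1, 13 without knockout IIAEK 2, 10 without knockout IIAEK 3, 7 without knockout vehicle 3, 6 without knockout vehicle 1 and 1 without knockout vehicle 2. Sterol transport genes (median 0.03, adjusted p = 0.809) and cholesterol synthesis genes (median -0.05, adjusted p = 0.448) were not called. The latter were lower within slide 1 (-0.30, adjusted p = 1.25e-05), without knockout vehicle 2 (-0.19, adjusted p = 0.00284) and without knockout IIAEK 3 (-0.10, adjusted p = 0.0278), but higher within slide 2 (0.27, adjusted p = 0.0189).

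The difference between the IIAEK effects of the genotypes asks whether the peptide needs Akp3. For drug-metabolizing genes the effect was lower in the knockout (median difference -0.48, 34 of 37 below 0, adjusted p = 5.07e-08, or 0.609 with an estimated correlation), with Ces2c (-0.72), Ces2a (-0.87), Ces1d (-0.72) and the quinone reductase gene Nqo1 (-0.62) leading. For glucocorticoid and fasting-response genes it was higher (median 0.18, adjusted p = 9.70e-04, or 0.609 with an estimated correlation), with Tsc22d3 (0.97), Ddit4 (1.47) and Fkbp5 (0.99) leading. Their list's mean was 3.17 in wild type under vehicle, 2.87 in wild type under IIAEK, 2.78 in knockout under vehicle and 2.84 in knockout under IIAEK. This difference, the IIAEK effect in wild type and the knockout effect under vehicle share the wild-type vehicle arrays. They are therefore not independent results, and the difference does not show that the peptide needs Akp3. For Abcg5 and Abcg8 the difference was -0.51 and -0.49 (adjusted p = 1 for both), so the larger values in wild type were not shown to depend on the genotype.

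Of single genes, 0 passed for this difference by limma (0 without the intensity trend), with 154 higher and 244 lower at an unadjusted p under 0.05. The count was 0 with slide as a block, 0 within slide 1, 35 within slide 2 and 1 without wild-type vehicle 3. Bnip5 (-1.96), S1pr1 (1.14), Clec1a (not well above background in wild type under vehicle), Casp4 (-1.53), Rnd1 (-1.17), Cxcl13 (2.25), Tppp (0.76) and Fosl2 (-0.52) had the smallest p, at adjusted p = 1. Other named genes were Npc1l1 (-0.12), Abca1 (-0.19), Slc15a1 (0.70), Akp3 (-0.33, a sign that changed between scalings), Alpi (-0.20), Alppl2 (0.10) and Alpl (-0.19). Akp3 and Alppl2 were 0.46 and 0.62 within slide 1 and -1.91 and -0.55 within slide 2. Slc15a1 (0.685 and -0.201) and Npc1l1 (-0.188 and 0.154) turned between the slides too, whereas Abca1 (-0.137 and -0.135) did not.

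For the difference, camera called 16 lists, 7 higher and 9 lower, against 14 with slide as a block. Drug-metabolizing and glucocorticoid lists stayed called without any 1 array. With slide as a block their medians were -0.58 and 0.24 (adjusted p = 5.74e-07 and 0.00836). Within slide 1 they were -0.44 and 0.39, and within slide 2 -0.57 and -0.34. With both tissue scores as covariates they stayed called, at -0.20 (adjusted p = 0.00282) and 0.15 (adjusted p = 0.00111). The number of called lists was 10 without wild-type vehicle 1, 8 without wild-type IIAEK 2 and 6 without knockout IIAEK 3. Cholesterol synthesis genes (median -0.02, adjusted p = 0.864) and sterol transport genes (median -0.12, adjusted p = 0.452) were not called. Across the 26107 features, which are not independent replicates, the IIAEK effects in wild type and knockout had a Pearson correlation of 0.0835 and a Spearman correlation of 0.0859, with the same sign in 52.9%. The Pearson value was 0.617 within slide 1, -0.0178 within slide 2 and -0.0359 with slide as a block, and between -0.161 without knockout IIAEK 1 and 0.368 without knockout IIAEK 3. On slide 1 the stomach-type mean was 3.191, 3.111 and 2.961 on the vehicle arrays and between -3.238 and -1.865 on the IIAEK arrays. Treatment and stomach-type content therefore cannot be told apart in either genotype on slide 1.

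Averaged over genotypes, groups of protein-folding, innate inflammatory and cell cycle genes were lower under IIAEK, by camera with its preset correlation. With an estimated correlation 0 lists were called (smallest adjusted p = 0.905). Cd14 (-0.68), Il33 (-0.87) and Cxcl1 (not well above background in knockout under IIAEK) led the innate list, Rrm1 (-0.43) the cell cycle list, and Creld2 (-0.40), Pdia6 (-0.29), Hspa5 (-0.25) and Manf (-0.28), which serve folding in the endoplasmic reticulum, the unfolded protein list. Limma called 0 genes (0 without the intensity trend), with 314 higher and 453 lower at an unadjusted p under 0.05, against 250 within slide 1, 58 within slide 2 and 0 with slide as a block. On slide 1 stomach-type genes were high on every vehicle array and low on every IIAEK array, so the count there cannot tell treatment from tissue content. The adhesion gene Ceacam10 (-1.14), the ribosome biogenesis gene Noc3l (-0.53), the coenzyme A synthesis gene Pank1 (0.45), Uspl1 (-0.34), Farsb (-0.49), Asb13 (0.39), Gpx2-ps1 (-0.94) and Grb7 (0.41) had the smallest p, with adjusted p = 1. Abcg8 was 0.37 (adjusted p = 1), Abcg5 0.18, Npc1l1 0.09, Abca1 0.21 and Slc15a1 0.48. Abca1 (0.48 and -0.25) and Slc15a1 (0.62 and -0.28) turned between slides 1 and 2. Abcg8 (0.17 and 0.67), Abcg5 (0.17 and 0.06) and Npc1l1 (0.13 and 0.08) did not.

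Camera called 15 lists in this average, 5 higher and 10 lower, 12 with slide as a block, with adjusted p = 0.905 under an estimated correlation for those named here. Unfolded protein response genes had a median of -0.10 with 22 of 27 below 0 (adjusted p = 0.00154; -0.08 with slide as a block, -0.03 and -0.18 within the slides) and lost the call without wild-type IIAEK 1 (adjusted p = 0.0562). Innate inflammatory genes had a median of -0.14 (adjusted p = 0.0025; -0.17 with slide as a block, -0.01 and -0.20 within the slides), not called without knockout vehicle 2 (0.0598) or knockout IIAEK 3 (0.0676). Both lists stayed called with the tissue scores as covariates (adjusted p = 7.45e-05 and 5.55e-04). Cell cycle genes (median -0.11, adjusted p = 6.96e-05; -0.10 with slide as a block, -0.24 and 0.07 within the slides) and oxidative phosphorylation genes (median 0.15, 40 of 41 above 0, adjusted p = 6.96e-05; 0.12 with slide as a block, 0.27 and -0.18 within the slides) stayed called without any 1 array but not with the tissue scores (0.164 and 0.0963). The call for oxidative phosphorylation also ended with quantile normalization (median 0.06, adjusted p = 0.0614). Alkaline phosphatases had a median of -0.27 with 4 of 4 below 0 (Akp3 -0.48, Alppl2 -0.30, Alpl -0.24, Alpi -0.05; adjusted p = 0.0439, or 0.199 with slide as a block, 0.304 with the tissue scores and 0.191 with normexp, where the median was -0.10; -0.44 and 0.16 within the slides). That call ended, at adjusted p from 0.0527 to 0.272, without any 1 array other than wild-type vehicle 2, wild-type IIAEK 3 or knockout vehicle 3. The averaged Akp3 value joins -0.315 in wild type with -0.643 in knockout, where the gene is deleted and its probe lay close to background. Its place in this list is therefore no measure of a response to the peptide. Sterol transport genes (median 0.05, adjusted p = 0.439) and cholesterol synthesis genes (median -0.07, adjusted p = 0.259) were not called. The latter were lower within slide 1 (-0.20, adjusted p = 1.29e-04) and without wild-type IIAEK 3 (adjusted p = 0.0331), knockout vehicle 2 (0.00521) or knockout IIAEK 3 (0.0346), but higher within slide 2 (0.18, adjusted p = 0.01). The effects of IIAEK in wild type and of the knockout under vehicle share the wild-type vehicle arrays, and correlated at 0.667 across genes against 0.499 in 100 simulations of unchanged groups (highest 0.532), with a covariance of 0.0919 against 0.056. The simulated arrays were independent, so what arrays share through slide, replicate number or tissue content is not in the simulated values, and the excess is not assigned to the peptide or the knockout.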

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

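The tests of stomach tissue, of treatment as a source of stomach-type genes, of chance clustering and strain DNA near Akp3, of slide as the source of the IIAEK lists, and the count of lists that the tissue scores add there, were chosen only after the result was seen.

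The effect of IIAEK differed between the genotypes for 16 gene groups by camera with its preset correlation, and for 0 with an estimated one. Drug-metabolizing genes (median -0.48, adjusted p = 5.07e-08) had the smallest p, and the effect on them was lower in knockout than in wild type. Glucocorticoid and fasting-response genes differed by 0.18 (adjusted p = 0.00097). The group means of this list and of the heat shock list were highest in wild type under vehicle (3.17 and 1.77). Lower in knockout than in wild type were also genes of the pancreas (-2.03, adjusted p = 6.75e-06), chylomicron assembly (-0.28, 0.00145), oxidative phosphorylation (-0.19, 0.00313), brush border digestion (-0.35, 0.00661), enterocyte villi (-0.22, 0.00687), PPAR-alpha targets (-0.20, 0.018), peptide transport (-0.18, 0.0376) and the interferon response (-0.12, 0.0376). Higher were stomach-type genes (3.26, adjusted p = 0.00168), genes of enteric neurons and glia (0.33, 0.00563), B cells (0.85, 0.00661), intestinal stem cells (0.29, 0.00687) and the cell cycle (0.08, 0.00808), and immediate early and heat shock genes (0.28, 0.0105). The drug-metabolizing and glucocorticoid lists stayed called without any 1 array, and the pancreatic list lost its call without wild-type vehicle 1 (adjusted p = 0.111). The other 13 lost theirs without knockout IIAEK 3 (adjusted p from 0.072 to 0.873), and some also without wild-type vehicle 1 (up to 0.3), wild-type vehicle 2 (up to 0.387), wild-type vehicle 3 (0.0732), wild-type IIAEK 1 (up to 0.256), wild-type IIAEK 2 (up to 0.41), wild-type IIAEK 3 (up to 0.231), knockout vehicle 1 (0.22), knockout vehicle 2 (up to 0.134), knockout vehicle 3 (0.16) or knockout IIAEK 1 (0.123). With slide as a block the lists of B cells (adjusted p = 0.0944), PPAR-alpha targets (0.0993), peptide transport (0.187) and interferon (0.0606) were not called. With quantile normalization those of oxidative phosphorylation (median -0.08, adjusted p = 0.0909), PPAR-alpha targets (0.0909), peptide transport (0.0718) and interferon (0.0909) were not called, and the medians of chylomicron assembly and the cell cycle were -0.17 and 0.18. With normexp the medians of stomach-type, B-cell and peptide transport genes were 2.16, 0.36 and -0.11. With both tissue scores as covariates the drug-metabolizing (adjusted p = 0.00282), glucocorticoid (0.00111), neuron (0.0344), B-cell (0.0499) and heat shock lists (0.00789) stayed called. Those of chylomicron assembly (0.338), oxidative phosphorylation (0.484), brush border digestion (0.631), enterocyte villi (0.638), PPAR-alpha targets (0.785), peptide transport (0.703), interferon (0.983), stem cells (0.167) and the cell cycle (0.931) lost their calls, as did the stomach-type (0.631) and pancreatic (0.931) lists. The lists of enteroendocrine (0.0347) and Paneth cells (2.84e-04), duodenal-type genes (0.0301) and ribosomal proteins (0.0344) became called.

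The first pattern is the high level of stomach-type genes on 6 of the 12 arrays. RNA from stomach in some samples is a candidate explanation: 7 stomach genes that were not on the list followed the list's mean, as deviations from the group means over the 12 arrays, with a median r of 0.971 (Spearman 0.853, exact one-sided p = 0.0147 over 1296 shuffles, r from 0.127 to 0.993, and 0.945 without the 2 arrays farthest from the median). A response to IIAEK stays open, since the list's mean differed by -3.27 in wild type and -0.28 in knockout, and an exact permutation test over 400 arrangements gave a two-sided p = 0.41. Brunner's glands of the duodenum itself make several of the listed genes, so the site of the piece taken may also differ between mice, which no label records.

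The second pattern is the knockout difference of genes near Akp3 on chromosome 1, where 10 of 197 other named genes within 20 Mb had p under 0.01 (5.08%; 8 lower and 2 higher), against 68 of 15373 elsewhere (0.442%). Chance clustering is argued against by windows of the same width around 1000 other genes, of which 0% held as many (highest 5). Content of stomach and pancreas is argued against as well, since 9 of the 10 kept p under 0.01 with the stomach-type and pancreatic scores as covariates. Other differences in tissue content were not tested. A candidate explanation is DNA of another strain, kept around the targeted gene through the breeding of the knockout. It stays open, because the excess near the gene (one-sided Fisher's exact p = 4.99e-08) is the observation that raised it and does not test it. A local effect of the deletion on its neighbours would give such an excess too and was not tested.

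The third pattern is the set of 14 lists that differed between IIAEK and vehicle in wild type by camera with its preset correlation, and none of which did with an estimated one. Stomach and pancreas content stays open as a source. With both scores as covariates 5 of the 12 lists other than those of the stomach and pancreas themselves stayed called in the same direction. Their medians went from -0.258 to -0.166 for glucocorticoid, -0.315 to -0.0981 for heat shock and -0.471 to -0.345 for B-cell genes. For erythroid genes the median went from -0.769 to -1.08, and for unfolded protein genes from -0.0589 to -0.166. But 10 lists not called before became called, so the covariates exchanged the members of the set and did not shrink it (14 and 15 lists). With slide as a block 11 of 14 lists stayed called, which does not test slide as the source, because each slide held as many vehicle as IIAEK arrays of wild type and the block could not move the medians. An effect of the peptide stays open, as does the difference between single mice, since each group held 3.

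Other splits of the same arrays were counted for each result. For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. There, IIAEK in wild type gave 0 genes (10 of the 10 splits as many, highest other 0) and 14 lists (5 of 10, highest other 22), and IIAEK in knockout 0 genes (10 of 10, highest other 0) and 3 lists (10 of 10, highest other 25). Knockout under vehicle gave 2 genes (1 of 10, highest other 1) and 19 lists (1 of 10, highest other 18), and knockout under IIAEK 2 genes (1 of 10, highest other 0) and 14 lists (6 of 10, highest other 18). Among the 4 splits that part all 3 replicate numbers, the real one included, the highest other counts of lists were 22 for IIAEK in wild type and 16 for knockout under vehicle. Of 100 splits, the averaged knockout count of 5 genes was reached in 2, the real one included, and 4 of the other splits called any gene. That count holds Akp3, the deleted gene, whose call the genotype fixed in advance, and the unnamed tag. The share of splits therefore draws on Akp3 and decides nothing about chance for the rest. The other 3 features were not tested apart from Akp3 and the tag, so for these chance stays open. For the 13 lists (68 of 100, highest other 30) chance was not excluded. Nor was it for the averaged IIAEK effect (0 genes, 100 of 100; 15 lists, 55 of 100, highest other 27) or for the difference between genotypes (0 genes, 100 of 100; 16 lists, 46 of 100, highest other 27). The highest other gene counts were 4321 for averaged IIAEK and 2645 for the averaged knockout, in splits that put all 5 arrays of slide 2 on 1 side, and 37 for the difference, in a split with those 5 arrays on the lower side, which points to slide as a structure of the samples. For the real groups, the counts with slide as a block were 0 for averaged IIAEK, 8 for the averaged knockout and 0 for the difference. The other splits were not run with slide as a block.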

How the results depend on the processing

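Gene-by-gene array weights and the tissue-score covariates were chosen after seeing the data; the other alternatives were fixed before. Counts are given in the order IIAEK in wild type, IIAEK in knockout, difference between genotypes, knockout under vehicle, knockout under IIAEK, averaged IIAEK and averaged knockout, where the reported gene counts are 0, 0, 0, 2, 2, 0 and 5 and the list counts 14, 3, 16, 19, 14, 15 and 13. Of 349 counts and correlations under an alternative, 258 stayed close to the reported one, 85 moved and 6 reversed, and of the values of called named genes 102 kept their call and 25 lost it. Akp3 kept its direction and its call in each knockout comparison under each alternative that measured it, with -6.16 to -5.88 under vehicle, -6.66 to -5.82 under IIAEK and -6.34 to -5.92 on average when 1 array was left out. Except where stated, the cause of a change was not tested. Normexp gave 14 lists for IIAEK in knockout and 3 genes for averaged knockout, quantile normalization 11 lists for IIAEK in knockout, and the deposited values 8 genes for averaged knockout. Keeping only probes well above background on all arrays removes Akp3 by construction and gave 0, 0 and 2 genes in the knockout comparisons. Without the intensity trend averaged knockout had 8 genes, and with only the 2 groups compared knockout under vehicle had 6. A 1.5-fold minimum changed no count. Slide as a block gave 5 lists for IIAEK in knockout, 8 genes for averaged knockout and a correlation of IIAEK effects of -0.0359, against 0.0835. On slide 1 stomach-type genes were high on every vehicle array and low on every IIAEK array, so treatment and stomach-type content cannot be told apart there. Slide 1 alone gave 257, 58, 0, 4, 8, 250 and 12 genes, 22 and 20 lists for IIAEK in wild type and knockout, and a correlation of 0.617. Slide 2 alone, with 1 residual degree of freedom, gave 0, 255, 35, 80, 14, 58 and 49 genes, 26 lists for IIAEK in knockout, 24, 25 and 22 for knockout under IIAEK and both averages, and a correlation of -0.0178. With replicate number as a block the gene counts were 0, 0, 0, 2, 2, 0 and 4 and the list counts 10, 3, 15, 17, 12, 13 and 14; where the numbers count as pairs, the lists of chylomicron assembly, sugar transport, MHC class II (adjusted p = 0.0806) and unfolded protein genes were lost for IIAEK in wild type and those of mucosal defence and innate signalling (adjusted p = 0.0673 for both) for knockout under vehicle, and no other call changed. 5 of the 12 arrays correlated best with an array of their own number. Array weights gave 0, 3928, 2, 564, 123, 2297 and 1182 genes and a correlation of 0.326; they gave knockout IIAEK 2 a weight of 56.7, against 0.322 and 0.13 for the other 2 of its group, so that group rests almost on 1 array. Gene-by-gene weights (4.9, 0.62 and 0.193 there) gave 0, 2, 0, 197, 8, 0 and 37 genes and 0.283. The stomach-type score gave 12, 6, 4 and 9 lists for IIAEK in knockout, the difference, knockout under vehicle and averaged IIAEK, and 5 and 9 genes for knockout under IIAEK and on average; both scores gave 11, 9 and 10 lists for IIAEK in knockout, the difference and knockout under vehicle, and 5 genes for knockout under IIAEK. Camera with an estimated correlation gave 0 lists in all 7. Leaving out 1 array, a group of 2 being assumed to vary like the others, gave genes from 0 to 17, 0 to 0, 0 to 1, 2 to 18, 2 to 4, 0 to 0 and 2 to 10, lists from 9 to 18, 1 to 15, 6 to 23, 13 to 20, 9 to 19, 10 to 19 and 8 to 22, and a correlation from -0.161 to 0.368. The counts of 17, 1 and 18 genes came without wild-type vehicle 3, 4 without knockout IIAEK 3, and for averaged knockout 2 without wild-type vehicle 1 or 2, knockout vehicle 1 or 2 or knockout IIAEK 2, 3 without knockout vehicle 3 and 10 without wild-type IIAEK 3. Of the lists, 9 for IIAEK in wild type came without wild-type IIAEK 1, 9 for knockout under IIAEK without wild-type IIAEK 3, and 8 and 22 for averaged knockout without wild-type IIAEK 3 and knockout IIAEK 3. For IIAEK in knockout there were 6, 1 and 7 lists without knockout vehicle 1, 2 and 3 and 15, 13 and 10 without knockout IIAEK 1, 2 and 3, and for the difference 10, 8 and 6 without wild-type vehicle 1, wild-type IIAEK 2 and knockout IIAEK 3. The correlation was also below 0 without wild-type IIAEK 1 (-0.0416), knockout vehicle 1 (-0.13) and knockout IIAEK 2 (-0.0872), and 0.247 without knockout vehicle 3. Rgp1 stayed between -2.37 and -1.99 and Utp14b between -1.16 and -1.04 without 1 array. Rgp1 lost its call with the mean of its probes (-1.13) and without wild-type vehicle 1 or 2, any 1 knockout vehicle array or knockout IIAEK 1 or 2, and Utp14b without any 1 array other than wild-type IIAEK 3. Utp14b also lost its call with normexp (-0.34, adjusted p = 1), no filter (adjusted p = 0.0982), each slide alone (0.368 and 0.455), the replicate block (0.0691) and both scores (0.0967). With 3 arrays per group, 2-fold changes were recovered in 39.1% of genes in simulated data of IIAEK in wild type. Those simulated genes and arrays were independent. Changes of that size were thus often missed in the simulation and may be missed here.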

Other observations

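The genes in this part were chosen after their values were seen. Slc15a2, which encodes the peptide transporter of kidney and other tissues, was low on all 3 arrays of wild type under IIAEK (-5.49, -4.64 and -4.80) against vehicle (-0.40, -1.89 and -2.14), and only the second of these IIAEK arrays was well above background (limma adjusted p = 0.999). In knockout it was low on 1 of 3 IIAEK arrays (-4.23, -0.35 and -0.47, against 0.15, -0.66 and 0.06 under vehicle), and the difference between the genotypes' effects was not called (limma adjusted p = 1). Chil3, a chitinase-like gene of macrophages and inflamed epithelium, had its highest levels in knockout under vehicle (1.23, -0.99 and 0.29) and was lower in knockout under IIAEK (-4.39, -6.65 and -3.35, the second not well above background). The renin gene Ren2 lay between -3.17 and -2.20 on the 6 wild-type arrays and between -1.58 and 0.64 on the 6 knockout arrays. It is a gene that some laboratory strains carry and others lack, and its position in the gene table is not on a chromosome sequence.

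Markers of lymphoid follicles were high on the arrays of wild-type vehicle 1 and 2. The follicle receptor gene Cr2 was at 2.12 and 1.08 there and between -3.44 and -1.70 on the other 10 arrays. Cxcl13 was at 2.09 and 1.64 on those arrays and 0.02 on wild-type vehicle 3, and Glycam1 at 0.15 and -0.32 against -2.08. Mup1, a gene of major urinary proteins, was at 1.38, 0.66 and 0.90 in wild type under vehicle, at 2.05 on wild-type IIAEK 3, at 1.07 on knockout IIAEK 3 and at -1.03 on knockout vehicle 1, the 6 arrays with high stomach-type genes, and between -6.99 and -4.54 on the others, none of them well above background. The liver gene Alb did not follow it, with -4.01, -3.47 and 1.94 in wild type under vehicle and -3.12 on wild-type IIAEK 3.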
